A study of Mus musculus with 10 samples.

How the data were processed

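Bulk RNA sequencing of mouse fibroblasts was analysed in 10 libraries, 4 of fibroblasts cultured alone, 3 of fibroblasts cocultured with WT ILC2s and 3 with IL13KO ILC2s. Per the labels, libraries were made with a low-input kit and sequenced as paired reads of 50 nt. The authors' notes list FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.7a, Picard, Salmon 1.6.0 and DESeq2 on the build GRCm38.p6, without stating which tool counted the reads, with which annotation or on which strand. The deposited count table gives counts, as whole numbers, for 22731 genes, and was used for all tests. A second deposited table gives a normalized signal. Multiplying that signal by a median-of-ratios size factor per library returned the counts for every gene within 0.05 counts, so it holds no further measurement and was not used here. Symbols, positions, GC content and transcript length came from the GENCODE annotation of the same build, which matched 22639 gene identifiers.

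Genes were kept by edgeR's filterByExpr, which left 16344. Counts were normalised by TMM in edgeR 4.0.16 (R 4.3.3), and a quasi-likelihood model with 1 coefficient per group was fitted to all 10 libraries. The 3 comparisons were WT coculture against monoculture, IL13KO coculture against monoculture and WT against IL13KO coculture. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called below 0.05. CPM are TMM-normalised, and log2 CPM use a prior count of 2. For a gene with no reads in a group, the fold is a lower bound against 3 counts over that group, and with 1 to 3 reads it is a ratio with an exact counting interval at 95% confidence.

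Before the data were examined, 30 gene lists (492 genes) were fixed for fibroblast states, pathways and other cell types, and the comparisons, the alternatives and the rule for naming genes were written down. The rule names, per comparison, the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 10 CPM in a group, up to 4 members per list with the smallest adjusted p, and 14 genes of the design. Predicted genes and identifiers with no symbol were left out, and members of lists that were not called could be. Genes named outside the rule, or in a comparison where it does not name them, such as Vcam1, Tgm2, Lum, Podn and Lrg1, were chosen after their values were seen. A gene that the rule names in a called list is not reported here. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. Lists were called at a Benjamini-Hochberg adjusted p below 0.05 over the lists of a comparison.

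The leukocyte level of a library is the mean log2 CPM of the leukocyte list, and groups were compared with exact two-sided permutation tests. For the correlation of fold changes, the shared monocultures were split 2 and 2. All 10 libraries were also simulated from the monoculture means, without differences between groups, in 20 draws. Alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter and a stricter one (1 CPM in 3 libraries), fits of only the groups compared, a replicate block, a test against a fold change of 1.5, leukocyte genes left out or the leukocyte level as a covariate, and leaving out each library in turn. Alternatives added later removed each library's trend with GC content and transcript length (loess, span 0.4), thinned the libraries to equal depth, or blocked by the column numbers of the count table. The model and the lists were tested on simulated data with 200 changed genes. All libraries and genes of the count table entered the analysis, and nothing was left out other than by the filter.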

Results

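Mouse fibroblasts were cultured alone or with group 2 innate lymphoid cells (ILC2s), tissue lymphocytes that carry no antigen receptor and secrete cytokines such as IL-5 and IL-13. The series title names the pancreas and a niche of fibroblast progenitors marked by Pi16. The starting fibroblasts were negative for CD45, Epcam and CD31 and positive for podoplanin and PDGFRα, and the ILC2s were positive for KLRG1. RNA was taken from fibroblasts that were sorted again after culture, and was sequenced in bulk. The labels form 3 groups. There were 4 libraries of fibroblasts alone (monoculture), 3 of fibroblasts kept with wild-type ILC2s (WT coculture) and 3 of fibroblasts kept with ILC2s that lack IL-13 (IL13KO coculture). For the sort after coculture the design text gives a gate positive for CD45, the antigen shared by white blood cells, although the starting fibroblasts lacked it. The labels assign no animal, day or culture to a library, so the spread between libraries may hold little or much of the spread between animals.

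Total counts were 12040837, 13611491, 10710410 and 14366199 in monocultures 1 to 4. They were 22087459, 19822804 and 18801744 in the WT cocultures, which carry the numbers 1, 3 and 4 in the count table, and 17661229, 17350329 and 17277432 in IL13KO cocultures 1 to 3. A floor of 3 counts corresponded to 0.209 to 0.2801 CPM (counts scaled to a common library total) in the monocultures, 0.136 to 0.160 in the WT cocultures and 0.170 to 0.174 in the IL13KO cocultures. Intervals and floors cover counting error only. Below, CPM are normalised group means ± SD (n = 4 monocultures, 3 WT and 3 IL13KO cocultures), and log2 fold changes are given ± SE.

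The gene absent from the knockout ILC2s was examined first. Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702 on GRCm38), which encodes IL-13, had 30, 120 and 121 reads in the WT cocultures and 0 reads in each of the 3 IL13KO cocultures and 4 monocultures. Its level in the WT cocultures was at least 77.8-fold that in the IL13KO cocultures, with 3 counts over the latter group as the floor. Il5, another cytokine gene of ILC2s, had 80, 265 and 371 reads with WT ILC2s and 30, 64 and 12 with IL13KO ILC2s, and 0 in every monoculture. Of its exon bases 27.1% are shared with a gene on the opposite strand, and no strand setting of the counting is given. Ptprc, which encodes CD45, had 6, 3 and 9 reads in the WT cocultures, 0, 1 and 0 in the IL13KO cocultures and 0 in every monoculture, and was too low to be tested.

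Libraries separated by group. The first principal component of log2 CPM held 65.7% of the variance and separated monocultures from cocultures, and the second held 13.9% and separated the cocultures from each other. The mean distance between libraries was 95.3 within the monocultures, 56.0 within the WT and 50.8 within the IL13KO cocultures. Between groups it was 183 for monoculture and WT coculture, 156 for monoculture and IL13KO coculture and 103 for the cocultures. Mitochondrial transcripts took 0.650 ± 0.112% of counts in monoculture, 0.470 ± 0.144% in the WT and 0.468 ± 0.0316% in the IL13KO cocultures. Transcripts of ribosomal proteins took 3.73 ± 0.166%, 2.697 ± 0.308% and 2.29 ± 0.131%.

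**Figure D1:**
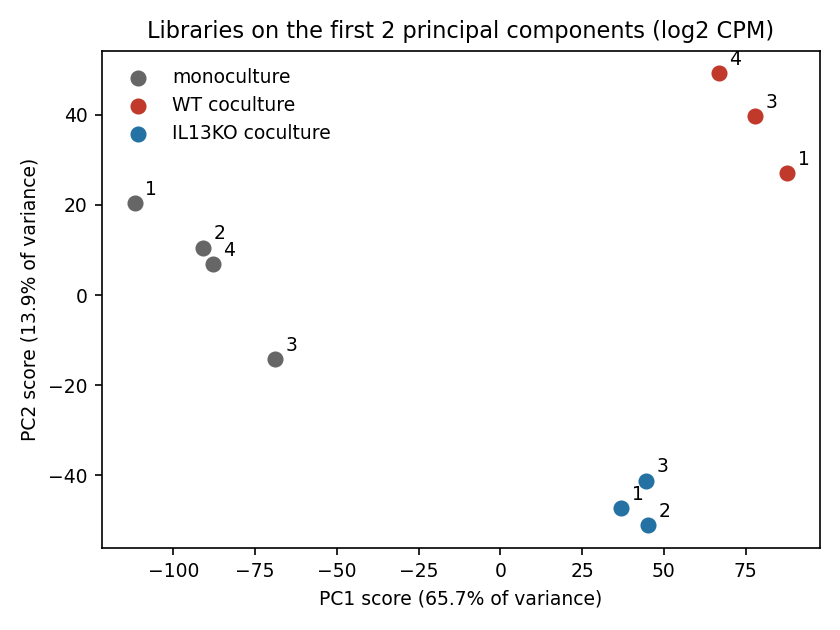
Scores of the 10 libraries on the first principal component (65.7% of variance) and the second (13.9%), computed from log2 CPM, with each point a library labelled by its number and coloured by group. Monocultures lie apart from cocultures on the first component and the WT from the IL13KO cocultures on the second.

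Coculture with wild-type ILC2s was set against monoculture to show what these lymphocytes change in fibroblasts. Lists of genes that respond to IL-4 or IL-13, of DNA replication and mitosis, of glycolysis and hypoxia and of NF-κB targets were called as higher by camera, and that of interferon-induced genes as lower. With an estimated correlation only the first call held (adjusted p = 0.0498, the others 0.255 to 0.532). Ccl11 (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955), the gene of the eosinophil chemokine eotaxin, stood at 100.1 ± 15.6 CPM in monoculture and 5938 ± 811 in the WT coculture (log2 fold change 5.89 ± 0.15). Pi16 (ENSMUSG00000024011, chromosome 17, 29317680 to 29330593), the progenitor marker, rose from 165 ± 30.2 to 1293 ± 253 CPM (2.97 ± 0.16). Grem1, which encodes a secreted antagonist of bone morphogenetic proteins (BMPs), fell from 92.6 ± 6.997 to 2.97 ± 1.41 CPM (-4.98 ± 0.31).

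Among the 10 named rises the largest fitted fold change was that of Chil4 (ENSMUSG00000063779, chromosome 3, 106201490 to 106219507), a chitinase-like gene, with 1 read in the monocultures and 285 ± 116 CPM in the WT coculture. Its ratio was 14020, with an exact 95% counting interval of 2515 to 553600. Chil3, its near-identical neighbour in sequence, stood at 12.3 ± 5.30 CPM, at least 201.4-fold above monoculture, and reads shared by the pair could be assigned to either. No monoculture read was found for Col6a5, a collagen VI chain, or Gpbar1, a bile acid receptor, which reached 32.2 and 18.8 CPM and lay at least 534.5-fold and 313.6-fold above monoculture. Il5, at 12.4 ± 8.27 CPM, lay at least 199.4-fold above. Car4, a carbonic anhydrase, rose from 0.190 ± 0.136 to 623 ± 115 CPM (11.56 ± 0.29), and Cxcl13, a chemokine for B cells, from 1.29 ± 0.847 to 445 ± 109 (8.42 ± 0.31). Gfra2, a receptor for GDNF family ligands, rose by 8.24 ± 0.39, and Csf2rb2, a cytokine receptor chain nearly identical to Csf2rb, by 7.75 ± 0.53. Myocd, which encodes the smooth-muscle coactivator myocardin, had 3 reads in monoculture and a ratio of 328 (interval 112 to 1592).

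The 10 named falls were led by Car3, a carbonic anhydrase of muscle and fat, from 49.2 ± 36.0 CPM to 3 reads in the WT cocultures, a ratio of 991 (interval 339 to 4808). Its level in the monocultures ranged from 0.444 to 87.2 CPM. limma-voom did not call Car3 (adjusted p = 0.242). Wdr72 fell from 10.6 ± 2.38 CPM to 2 reads, a ratio of 325 (interval 89.5 to 2690). Aspn, which encodes the matrix proteoglycan asporin, fell from 185 ± 57.9 to 4.78 ± 0.0975 CPM, and Ctla2a, part of whose exons other annotated genes share, from 232 ± 42.5 to 5.22 ± 0.899. Log2 fold changes were -5.33 ± 0.31 for Limch1, -5.29 ± 0.33 for Inmt, -5.07 ± 0.31 for Nell2, -4.91 ± 0.36 for Cemip, a hyaluronan-degrading protein, and -4.79 ± 0.31 for Mamdc2.

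Of the list of genes that respond to IL-4 or IL-13 through STAT6, 12 of 14 tested genes rose and 1 fell (13 adjusted over the list alone, camera adjusted p = 1.73e-05, adjusted p = 0.0498 with an estimated correlation). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), the gene of the IL-33 receptor ST2, rose from 6.89 ± 1.501 to 1298 ± 133 CPM, and Il13ra2, the decoy receptor for IL-13, from 4.43 ± 1.96 to 462 ± 56.2. Cish, a STAT-induced feedback inhibitor, rose by 5.62 ± 0.22, and Il4ra, the receptor chain shared by IL-4 and IL-13, by 3.45 ± 0.23. Vcam1, an adhesion molecule gene, was the member that fell (-0.48 ± 0.11). Il13ra1, the other chain of the IL-13 receptor, was at 126 ± 22.9 and 162 ± 18.3 CPM (0.36 ± 0.13, edgeR adjusted p = 0.0302). That call ended without monoculture 3 or 4 or WT coculture 3 (edgeR adjusted p = 0.0638, 0.0790 and 0.152), with upper-quartile scaling (0.24, 0.133) and with only these groups in the fit (0.0570). Il1rl1 and Arg1 stand in both this list and that of ILC2 markers.

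Of the DNA replication and mitosis genes, 23 of 24 tested genes rose and 0 fell (23 adjusted over the list alone, camera adjusted p = 1.12e-09, adjusted p = 0.331 with an estimated correlation). Mcm6, a subunit of the replicative helicase, rose from 29.2 ± 4.64 to 138 ± 8.60 CPM, and Ccnb1, which encodes cyclin B1, from 21.3 ± 3.55 to 145 ± 4.40. Birc5, or survivin, rose by 2.54 ± 0.15 and Rrm2, a subunit of ribonucleotide reductase, by 1.95 ± 0.12. Of the glycolysis and hypoxia genes, 15 of 19 tested genes rose and 2 fell (17 adjusted over the list alone, camera adjusted p = 0.00185, adjusted p = 0.501 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose by 2.14 ± 0.16 and Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 2.15 ± 0.14, as did Eno1, an enolase gene with the near-identical copy Eno1b, by 1.43 ± 0.12 and P4ha1, a collagen prolyl hydroxylase gene, by 1.24 ± 0.10. Of the inflammatory NF-κB targets, 17 of 21 tested genes rose and 2 fell (19 adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.255 with an estimated correlation). Chemokine genes Cxcl5 (2.59 ± 0.14), Ccl2 (365 ± 51.8 to 2609.5 ± 142 CPM) and Ccl7 (750.0 ± 144 to 3738 ± 446) rose, whereas Saa3, an acute-phase gene, fell from 1373 ± 199 to 141 ± 19.4 CPM.

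Of the unfolded protein and amino acid stress genes, 10 of 18 tested genes rose and 3 fell (13 adjusted over the list alone, camera adjusted p = 0.0422, adjusted p = 0.501 with an estimated correlation). Hspa5, the endoplasmic reticulum chaperone BiP, rose from 2550.0 ± 239 to 5864 ± 733 CPM, and Psat1, an enzyme of serine synthesis, by 1.87 ± 0.10. Sdf2l1 and Creld2, which encode endoplasmic reticulum proteins, rose by 1.51 ± 0.10 and 1.23 ± 0.10. This list's call ended without monoculture 1, 3 or 4 or WT coculture 4 (camera adjusted p = 0.0534, 0.0515, 0.0556 and 0.0677), with the GC and length trend removed (0.0664) and with the block by column number (0.0506). Of the interferon-induced genes, 1 of 19 tested genes rose and 14 fell (15 adjusted over the list alone, camera adjusted p = 0.00425, adjusted p = 0.532 with an estimated correlation). Gbp2, an interferon-induced GTPase, fell from 62.1 ± 20.1 to 15.2 ± 0.809 CPM, and Irf9, a subunit of the interferon-activated transcription factor, fell too (-1.28 ± 0.16). Irgm1 and Gbp3, GTPase genes of the same kind, fell as well (-1.92 ± 0.23 and -3.22 ± 0.40).

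Markers of fibroblast states moved both ways. Of the markers of Pi16-positive progenitors, 11 of 21 tested genes rose and 5 fell, and of the markers of Col15a1-positive parenchymal fibroblasts, 6 of 18 tested genes rose and 7 fell. Neither list was called (camera adjusted p = 0.188 and 0.444). Cd34, a sialomucin of progenitor cells, rose from 10.7 ± 3.80 to 239 ± 24.1 CPM, and Wnt2 by 5.33 ± 0.26. Dpp4, the peptidase that marks the same cells, fell from 11.9 ± 4.97 to 2.20 ± 0.485 (-2.45 ± 0.38), and Ly6c1 was at 59.7 ± 5.83 and 48.9 ± 4.51 (edgeR adjusted p = 0.0634, called without monoculture 3, 0.0293, and with upper-quartile scaling, 0.0126). Apoe, which encodes apolipoprotein E, fell from 813 ± 112 to 53.2 ± 17.0 CPM. Col15a1, a basement membrane collagen, was at 19.3 ± 5.38 and 32.1 ± 13.6 CPM (0.75 ± 0.28, edgeR adjusted p = 0.0329), overlapped between groups, and turned to -0.21 with the GC and length trend removed. That call also ended without monoculture 2 or 4 or WT coculture 1 or 3 (edgeR adjusted p = 0.0853, 0.0870, 0.188 and 0.114), with upper-quartile scaling (0.0667), by limma-voom (0.0585) and with only these groups in the fit (0.0558).

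The sort markers were examined too. Pdgfra went from 372 ± 4.82 to 633 ± 100.3 CPM (0.77 ± 0.11) and Pdpn from 259 ± 27.8 to 328 ± 43.6 (0.34 ± 0.11), the latter not called without WT coculture 3 (edgeR adjusted p = 0.0978) or with upper-quartile scaling (0.22, 0.0933). Il33, the alarmin that activates ILC2s, was at 323 ± 80.2 and 327 ± 45.7 CPM (edgeR adjusted p = 0.934). The other pathway lists were not called (camera adjusted p from 0.0750 to 0.987). Their members that rose and fell numbered 13 and 4 of 22 for fibrillar matrix, 9 and 3 of 19 for growth factor and ERK genes, 4 and 9 of 18 for contractile genes and 8 and 8 of 18 for matrix proteases. The numbers were 12 and 5 of 20 for sterol synthesis, 3 and 3 of 14 for antigen presentation, 5 and 3 of 14 for ILC2 niche factors, 3 and 8 of 13 for complement, 2 and 6 of 14 for p53 targets, 5 and 8 of 15 for adipogenic genes and 4 and 5 of 12 for NRF2 targets. Fibrillar matrix was called without monoculture 3 (camera adjusted p = 0.0363).

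Markers of other cells were read as possible carry-over. Of the ILC2 markers, 8 of 11 tested genes rose and 1 fell (9 adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.501 with an estimated correlation), with Hlf, a transcription factor gene, rising from 2.51 ± 1.17 to 36.5 ± 3.82 CPM. The ILC2 call ended without monoculture 3, WT coculture 3 or 4, or IL13KO coculture 1 or 3 (camera adjusted p = 0.0515, 0.0649, 0.0677, 0.0644 and 0.0518). Of the leukocyte genes, 3 of 6 tested genes rose and 0 fell (camera adjusted p = 0.162, called without WT coculture 1, 0.0222, or IL13KO coculture 2, 0.0400). Cd53, a tetraspanin of white blood cells, rose from 3.13 ± 0.760 to 103.6 ± 10.04 CPM. Lyz2, the lysozyme gene of macrophages, fell from 53.4 ± 1.97 to 2.85 ± 0.581, and Rgs5, a pericyte marker, from 51.4 ± 12.3 to 8.54 ± 1.63. Whether the Lyz2 reads of the monocultures came from macrophages or from the fibroblasts was not tested. Ptprc had 0 reads in each monoculture, and Cd53 had 40, 29, 43 and 43. Members that rose and fell, in lists not called, numbered 1 and 1 of 3 for macrophages, 1 and 1 of 2 for T and B cells, 1 and 0 of 2 for endothelium, 1 and 1 of 2 for acinar cells, 2 and 1 of 5 for ductal epithelium, 2 and 1 of 7 for mesothelium, 0 and 5 of 8 for mural and stellate cells and 0 and 0 of 3 for Schwann cells. Mural and stellate markers were called once the GC and length trend was removed (camera adjusted p = 0.00509), and no islet marker was abundant enough to test. The median, mean and test differed in sign for the parenchymal, T and B cell, acinar and mesothelial lists.

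**Figure D2:**
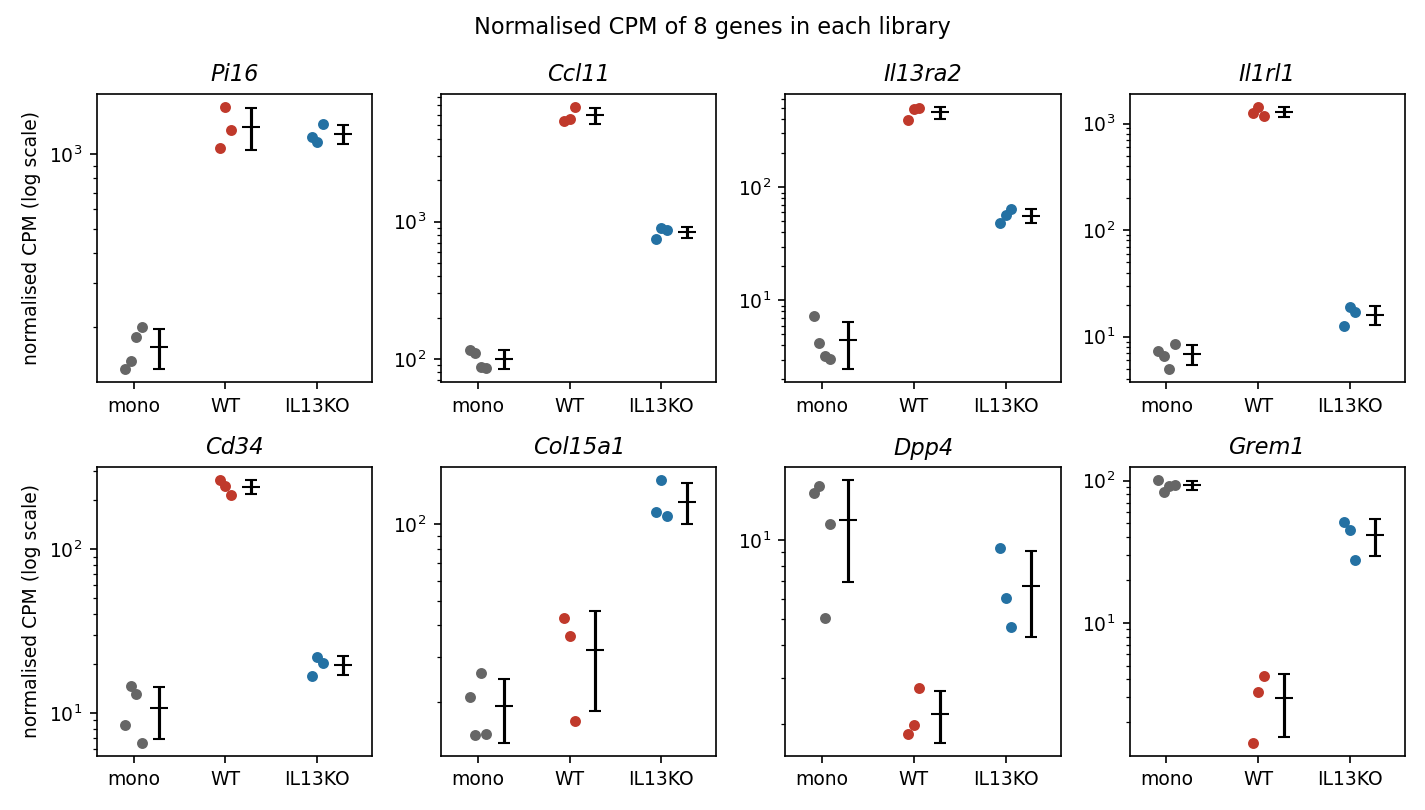
Normalised CPM (log scale) of 8 genes in each library, with a point per library and a bar for the group mean ± SD (n = 4 monocultures, 3 WT and 3 IL13KO cocultures). Pi16 was close in both cocultures, whereas Ccl11, Il13ra2, Il1rl1 and Cd34 stood higher in the WT than in the IL13KO coculture.

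Over all genes, edgeR's quasi-likelihood test called 10212 of the 16344 tested (62.5%) at a Benjamini-Hochberg adjusted p below 0.05, of which 5355 were higher and 4857 lower in the WT coculture. The balance turned with upper-quartile scaling (4821 higher, 5636 lower) and with the GC and length trend removed (4698 and 5023). At least a doubling was fitted for 3532 of them and at least a halving for 1960. Counts of calls depend on the size asked for, and 5884 genes passed a test against a fold change of 1.5. Fold changes correlated with GC content across genes (rho = 0.339), and genes are not independent replicates. With the GC and length trend removed, named genes whose fold moved by over 1.5 times and that stayed called were Aspn (-4.50), Ccl11 (6.57), Ccl2 (3.42), Ccl7 (3.002), Cd53 (5.72), Cish (4.98), Csf2rb2 (7.10), Cxcl13 (9.15), Il13ra2 (7.35), Il4ra (2.56) and Pi16 (2.24). Col15a1 moved as far and lost its call (-0.21, edgeR adjusted p = 0.488). So did the list members Col4a2 (1.30 to 0.10, 0.666) and Tgm2 (0.88 to 0.023, 0.893), not named above for this comparison. Single libraries moved Csf2rb2 (9.28 without monoculture 3), Gfra2 (9.86 without monoculture 2) and Cemip (-5.69 without WT coculture 3) as far. Fitted log2 fold changes of genes with 0 to 3 reads in a group moved as far for Wdr72 (-8.03, and -10.38 without WT coculture 1), Myocd (8.18, and 9.22 without monoculture 3), Car3 (-9.75, and -10.59 without WT coculture 4) and Chil4 (13.34, and 15.21 without monoculture 2). By limma-voom they were -8.19 for Car3, 8.13 for Chil3 (10.65 by edgeR), 12.30 for Chil4, 9.62 for Col6a5 (12.04), 8.87 for Gpbar1 (11.26) and 7.91 for Il5 (10.66).

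Coculture with ILC2s that lack IL-13 was set against the same monocultures to show what remains without that cytokine. Lists of type 2 response genes, fibrillar matrix, DNA replication and mitosis, and NF-κB targets were called as higher by camera. None of these calls held with an estimated correlation (adjusted p from 0.183 to 0.716). Ccl11 stood at 841 ± 78.4 CPM against 100.1 ± 15.6 in monoculture (3.07 ± 0.13), and Pi16 at 1208 ± 107 against 165 ± 30.2 (2.87 ± 0.16). Loxl1, which encodes an enzyme that crosslinks elastin and collagen, rose from 110.2 ± 44.8 to 1983 ± 89.8 CPM (4.17 ± 0.25). Col15a1 rose from 19.3 ± 5.38 to 123 ± 22.8 CPM (2.68 ± 0.28).

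The named rises ran from 4.65 to 6.39 on the log2 scale. S1pr3, a receptor for sphingosine 1-phosphate, rose from 20.3 ± 6.47 to 510.0 ± 74.3 CPM, Rtn4rl2, a Nogo receptor relative, from 2.02 ± 0.830 to 118.0 ± 15.9, and Car4 from 0.190 ± 0.136 to 13.5 ± 2.35. Log2 fold changes were 6.16 ± 0.56 for Csf2rb2, 5.17 ± 0.53 for Adra1d, an adrenergic receptor, 4.92 ± 0.35 for Map3k11 and 4.72 ± 0.38 for Dctn1, a dynactin subunit. Atg9a, of whose exon bases other genes share 32.6%, rose by 6.39 ± 0.44. Pcdhgb6 and Pcdhgc5 rose by 4.97 ± 0.53 and 4.80 ± 0.68 but share 45.2% and 39.6% of their exon bases with the other γ-protocadherins, so their reads could be assigned to either.

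The 5 genes among the named falls of both cocultures (Aspn, Wdr72, Inmt, Ctla2a and Mamdc2) fell less here than with WT ILC2s, each passing between the cocultures. Aspn fell from 185 ± 57.9 to 19.2 ± 1.56 CPM (-3.27 ± 0.22) and Ctla2a from 232 ± 42.5 to 43.4 ± 11.9 (-2.42 ± 0.20). Nrep fell from 155 ± 41.4 to 25.5 ± 2.50 CPM. Log2 fold changes were -2.99 ± 0.36 for Wdr72, -2.69 ± 0.26 for Inmt, -2.59 ± 0.28 for Zrsr1, -2.30 ± 0.25 for Mamdc2 and -2.14 ± 0.25 for Snhg12, a host transcript of small nucleolar RNAs. For the interferon-induced genes Rtp4 and Ifit1 they were -2.30 ± 0.49 and -2.09 ± 0.60, and -1.49 and -1.37 without monoculture 2.

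Of the genes that respond to IL-4 or IL-13, 10 of 14 tested genes rose and 0 fell (10 adjusted over the list alone, camera adjusted p = 0.00139, adjusted p = 0.183 with an estimated correlation). Il4ra rose from 54.8 ± 14.3 to 834 ± 8.83 CPM, Il13ra2 from 4.43 ± 1.96 to 56.4 ± 8.19 and Il1rl1 from 6.89 ± 1.501 to 16.1 ± 3.25. Cish rose by 3.20 ± 0.23 and Il13ra1 by 0.50 ± 0.13, while Chil3 and Chil4 had no read in this coculture. Of the fibrillar matrix genes, 19 of 22 tested genes rose and 3 fell (22 adjusted over the list alone, camera adjusted p = 7.26e-04, adjusted p = 0.716 with an estimated correlation). Col6a1, a collagen VI chain, rose from 86.1 ± 27.1 to 926 ± 114 CPM, Col6a2 by 3.04 ± 0.22 and Lox, a lysyl oxidase, from 739 ± 37.9 to 2132 ± 73.1. Lum, the gene of the proteoglycan lumican, was among the members that fell, from 635 ± 201 to 234 ± 14.7.

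Of the DNA replication and mitosis genes, 20 of 24 tested genes rose and 1 fell (21 adjusted over the list alone, camera adjusted p = 0.00139, adjusted p = 0.716 with an estimated correlation). Mcm6 rose from 29.2 ± 4.64 to 53.5 ± 5.18 CPM and Plk1, a mitotic kinase gene, from 5.72 ± 2.21 to 28.1 ± 5.34. Mcm2, of the same helicase, rose by 2.48 ± 0.30 and Cenpe, a mitotic kinesin gene, by 3.27 ± 0.49. Of the NF-κB targets, 11 of 21 tested genes rose and 1 fell (12 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.552 with an estimated correlation), and the call ended with the replicate block (camera adjusted p = 0.0604). Nfkb2 and Relb, which encode subunits of the noncanonical NF-κB dimer, rose by 2.49 ± 0.23 and 1.81 ± 0.24, Icam1, an adhesion molecule gene, by 1.19 ± 0.13 and Ccl2 from 365 ± 51.8 to 653 ± 47.4 CPM. Cxcl13 rose from 1.29 ± 0.847 to 29.0 ± 3.24 and Il33 from 323 ± 80.2 to 627 ± 34.6.

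Of the progenitor markers, 9 of 21 tested genes rose and 4 fell, and of the parenchymal markers, 11 of 18 tested genes rose and 5 fell, without a call (camera adjusted p = 0.552 and 0.464). Cd34 rose from 10.7 ± 3.80 to 19.6 ± 2.67 CPM (0.88 ± 0.22), Cd248, or endosialin, from 23.7 ± 12.9 to 368 ± 37.6, and Col4a2, a basement membrane collagen chain, from 12.3 ± 4.53 to 82.8 ± 5.87. Dpp4 was at 6.70 ± 2.40 CPM (-0.83 ± 0.35, edgeR adjusted p = 0.0545), and was called without monoculture 3 or IL13KO coculture 1 (0.00302 and 0.0294), by DESeq2 (0.0396), with upper-quartile scaling (0.0317) and with the GC and length trend removed (0.0288). Ly6c1 was at 66.9 ± 11.1 CPM (edgeR adjusted p = 0.283, called with that trend removed, 0.63, 3.90e-04). Pdgfra rose to 747 ± 86.6 CPM (1.01 ± 0.11) and Pdpn was at 285 ± 16.6 (0.287, called with that trend removed, 0.37, 0.00835).

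The other pathway lists were not called (camera adjusted p from 0.0739 to 0.989). Members that rose and fell numbered 1 and 9 of 19 for interferon-induced genes, 9 and 2 of 19 for growth factor and ERK genes, 6 and 7 of 18 for contractile genes, 10 and 3 of 18 for matrix proteases, 9 and 6 of 20 for sterol synthesis and 11 and 3 of 19 for glycolysis and hypoxia. For amino acid stress they numbered 9 and 3 of 18, for antigen presentation 4 and 5 of 14, for ILC2 niche factors 6 and 1 of 14, for complement 3 and 3 of 13, for p53 targets 0 and 4 of 14, for adipogenic genes 6 and 7 of 15 and for NRF2 targets 4 and 4 of 12. The interferon list was called, as lower, without monoculture 1 or 3, WT coculture 4 or IL13KO coculture 1 (camera adjusted p = 0.0410, 0.0256, 0.0459 and 0.0379), with the replicate block (0.0155), with the GC and length trend removed (0.0282) and after thinning to equal depth (0.0476). The list of p53 targets was called, as lower, with that trend removed (0.0203). Of the ILC2 markers, 5 of 11 tested genes rose and 0 fell, and of the leukocyte genes, 1 of 6 tested genes rose and 0 fell, neither list called (0.391 and 0.492). Il5 lay at least 34.3-fold above monoculture (fitted log2 fold change 8.04, and 7.28 without IL13KO coculture 2, 7.09 by DESeq2 and 5.37 by limma-voom), Cd53 rose from 3.13 ± 0.760 to 16.4 ± 3.32 CPM, and Lyz2 fell to 23.8 ± 1.23. In lists not called, members that rose and fell numbered 0 and 1 of 3 for macrophages, 0 and 0 of 2 for T and B cells, 0 and 0 of 2 for endothelium, 1 and 1 of 2 for acinar cells, 1 and 0 of 5 for ductal epithelium, 2 and 1 of 7 for mesothelium, 3 and 0 of 8 for mural and stellate cells and 0 and 0 of 3 for Schwann cells. Median, mean and test differed in sign for the complement, adipogenic, antigen presentation, T and B cell and macrophage lists.

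In total, edgeR called 9384 of the 16344 genes (57.4%), 4927 higher and 4457 lower than in monoculture. The balance turned with upper-quartile scaling (4490 higher, 5263 lower) and with the GC and length trend removed (3847 and 4370). A doubling or more was fitted for 3198 and a halving or more for 811. Fold changes correlated with GC content across genes (rho = 0.404) and with transcript length (rho = 0.301). A test against a fold change of 1.5 passed 4234 genes. With the GC and length trend removed, named genes whose fold moved by over 1.5 times, all still called, were Adra1d (4.19), Aspn (-2.60), Atg9a (5.43), Ccl11 (3.86), Ccl2 (1.54), Cd248 (2.95), Cd53 (3.06), Cish (2.48), Col15a1 (1.59), Col4a2 (1.31), Col6a1 (2.38), Col6a2 (2.12), Csf2rb2 (5.44), Cxcl13 (5.30), Dctn1 (3.49), Il4ra (2.92), Loxl1 (2.98), Map3k11 (3.57), Nfkb2 (1.24), Pcdhgb6 (4.195), Pcdhgc5 (3.95), Pi16 (2.05), Relb (0.94) and Rtn4rl2 (5.03). Csf2rb2 and Pcdhgc5 moved as far without monoculture 3 (7.69 and 5.97), Cenpe and Pcdhgb6 without monoculture 4 (4.07 and 5.90) or with the replicate block (4.07 and 5.93), and Pcdhgb6 and Pcdhgc5 by limma-voom (5.83 and 5.77).

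The cocultures were compared with each other to show what differs when the ILC2s lack IL-13. Il5 was lower with IL13KO ILC2s too (106 against 716 reads), and the leukocyte level lay 1.02 lower. A difference in the number or state of the ILC2s therefore cannot be told apart from the loss of IL-13. Lists of type 2 response genes, replication and mitosis, glycolysis and NF-κB targets were called as higher with WT ILC2s by camera, and those of matrix proteases and adipogenic, parenchymal and mural genes as lower. With an estimated correlation the type 2 and mural calls held (adjusted p = 0.0275 each), and those of the other lists named here did not (0.0913 to 0.230). Il1rl1 stood at 1298 ± 133 CPM with WT and 16.1 ± 3.25 with IL13KO ILC2s (log2 fold change 6.33 ± 0.20), and Ccl11 at 5938 ± 811 and 841 ± 78.4 (2.82 ± 0.15). Cd34 was 3.61 ± 0.23 higher with WT ILC2s, whereas Pi16 was at 1293 ± 253 and 1208 ± 107 CPM (0.098 ± 0.16, edgeR adjusted p = 0.710). Mmp3, which encodes the matrix protease stromelysin 1, stood at 116 ± 23.01 CPM with WT and 1301 ± 201 with IL13KO ILC2s (-3.49 ± 0.20).

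The genes raised most in the WT over the IL13KO coculture included Chil4 and Chil3, which had no read with IL13KO ILC2s and lay at least 4816-fold and 207.6-fold higher with WT ILC2s. Log2 fold changes were 6.13 ± 0.53 for Col6a5, 5.53 ± 0.21 for Car4, 5.41 ± 0.39 for Gpbar1 and 4.82 ± 0.33 for Myocd. Nt5e, the ectonucleotidase CD73, was 5.11 ± 0.58 higher, Tmem108 4.96 ± 0.66 and Ddx4, an RNA helicase gene known from germ cells, 4.95 ± 0.55. Among the named falls, Grem1 differed by -3.82 ± 0.31 and Cemip by -5.13 ± 0.37. Ace, the angiotensin-converting enzyme, was -4.43 ± 0.42, Wfdc17 -4.27 ± 0.24, Nell2 -4.20 ± 0.31, Fabp7, a fatty acid binding protein, -3.93 ± 0.31, and Ngfr, the low-affinity neurotrophin receptor, -3.64 ± 0.38. Saa1, an acute-phase gene close in sequence to Saa2, differed by -3.66 ± 0.35, and Clu, or clusterin, by -3.40 ± 0.34.

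Of the genes that respond to IL-4 or IL-13, 9 of 14 tested genes rose and 2 fell in the WT over the IL13KO coculture (12 adjusted over the list alone, camera adjusted p = 1.05e-05, adjusted p = 0.0275 with an estimated correlation). Il13ra2 differed by 3.04 ± 0.22 and Cish by 2.42 ± 0.19, but Il4ra (-0.48 ± 0.23, edgeR adjusted p = 0.156) and Il13ra1 (-0.14 ± 0.14, 0.519) did not pass. Tgm2, a transglutaminase gene, went the other way (-1.68 ± 0.21), as did Vcam1 (-0.56 ± 0.12). Of the replication and mitosis genes, 24 of 24 tested genes rose and 0 fell (24 adjusted over the list alone, camera adjusted p = 3.61e-16, adjusted p = 0.0913 with an estimated correlation), with Birc5 at 80.9 ± 11.3 and 23.6 ± 5.10 CPM. Tyms, or thymidylate synthase, was 1.38 ± 0.12 higher, Cdk1, the mitotic kinase gene, 1.22 ± 0.11 and Mcm6 1.37 ± 0.13. Of the glycolysis and hypoxia genes, 13 of 19 tested genes rose and 0 fell (13 adjusted over the list alone, camera adjusted p = 8.11e-06, adjusted p = 0.230 with an estimated correlation), with P4ha1 0.82 ± 0.11 higher, Tpi1, an enzyme of glycolysis, 0.81 ± 0.12, Pdk1 0.99 ± 0.15 and Slc2a1 1.08 ± 0.17. Of the NF-κB targets, 11 of 21 tested genes rose and 4 fell (16 adjusted over the list alone, camera adjusted p = 0.00385, adjusted p = 0.127 with an estimated correlation), with Ccl2 1.998 ± 0.12, Cxcl5 1.66 ± 0.15 and Ccl7 1.38 ± 0.15 higher and Saa3 -2.44 ± 0.15. Of the unfolded protein and amino acid stress genes, 8 of 18 tested genes rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 0.00188, adjusted p = 0.177 with an estimated correlation), Hspa5 standing at 5864 ± 733 and 2936 ± 104.0 CPM and Psat1, Sdf2l1 and Creld2 1.38 ± 0.11, 1.24 ± 0.11 and 0.98 ± 0.11 higher.

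Lists lower with WT ILC2s included matrix proteases, of which 1 of 18 tested genes rose and 7 fell (10 adjusted over the list alone, camera adjusted p = 2.46e-04, adjusted p = 0.0913 with an estimated correlation). Mmp10 and Mmp13 were -3.17 ± 0.18 and -2.77 ± 0.20, and Adamts5, an aggrecanase gene, was -1.25 ± 0.12. Of the adipogenic genes, 1 of 15 tested genes rose and 10 fell (11 adjusted over the list alone, camera adjusted p = 1.27e-04, adjusted p = 0.0913 with an estimated correlation), Cebpa and Pparg, the transcription factors of fat cell differentiation, at -2.32 ± 0.24 and -1.08 ± 0.14, and Fabp4, a fatty acid binding protein of fat cells, and Lpl, or lipoprotein lipase, at -1.71 ± 0.18 and -1.25 ± 0.14. Of the complement genes, 1 of 13 tested genes rose and 8 fell (12 adjusted over the list alone, camera adjusted p = 0.00243, adjusted p = 0.288 with an estimated correlation), with Cd59a, an inhibitor of the membrane attack complex, at -2.01 ± 0.16 and Cd55, which restrains C3 convertase, at 1.75 ± 0.16. C4b and C1s1, of the classical pathway and each with a close paralog (C4a and C1s2), were -2.44 ± 0.23 and -1.14 ± 0.14. Of the contractile and TGF-β target genes, 0 of 18 tested genes rose and 8 fell (8 adjusted over the list alone, camera adjusted p = 0.00943, adjusted p = 0.310 with an estimated correlation), with Ltbp2, which encodes a protein of elastic microfibrils, at -1.90 ± 0.23. Itga11, a collagen receptor chain, was -1.45 ± 0.24, Tgfbi -0.78 ± 0.15 and Cdh11, a cadherin gene, -0.51 ± 0.098.

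Of the parenchymal fibroblast markers, 1 of 18 tested genes rose and 10 fell (13 adjusted over the list alone, camera adjusted p = 8.11e-06, adjusted p = 0.127 with an estimated correlation). Apoe stood at 53.2 ± 17.0 CPM with WT and 467 ± 65.3 with IL13KO ILC2s, Col15a1 at 32.1 ± 13.6 and 123 ± 22.8 (-1.93 ± 0.30) and Smoc2, a matricellular gene, at 145 ± 24.4 and 577 ± 40.5. Tcf21, a transcription factor gene, was -2.27 ± 0.19 and Gas6, a ligand of receptor kinases, -2.09 ± 0.19. Of the progenitor markers, 8 of 21 tested genes rose and 6 fell (camera adjusted p = 0.0813), with Wnt2 4.31 ± 0.26 higher and Limch1 -4.34 ± 0.31. Dpp4 was -1.61 ± 0.39, a call that ended without IL13KO coculture 1 (edgeR adjusted p = 0.0582). Ly6c1 was -0.45 ± 0.13, not called without WT coculture 1 or 3 or IL13KO coculture 2 or 3 (edgeR adjusted p = 0.0903, 0.109, 0.0640 and 0.142) or with the block by column number (0.0621). Il33 was -0.94 ± 0.18, while Pdgfra (-0.24 ± 0.12, edgeR adjusted p = 0.167, called without WT coculture 1, 0.0277) and Pdpn (0.20 ± 0.12, 0.245) did not pass.

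Of the sterol synthesis genes, 8 of 20 tested genes rose and 2 fell (10 adjusted over the list alone, camera adjusted p = 0.00894, adjusted p = 0.230 with an estimated correlation), with Fdps, part of whose exons another annotated gene shares, at 0.56 ± 0.098, Stard4 at 0.69 ± 0.15 and Hsd17b7 at -0.65 ± 0.14, and the call ended without WT coculture 1 (camera adjusted p = 0.0546). Of the interferon-induced genes, 0 of 19 tested genes rose and 7 fell (10 adjusted over the list alone, camera adjusted p = 0.0450, adjusted p = 0.638 with an estimated correlation), with Gbp2 at -1.51 ± 0.25, Ifi47 at -1.40 ± 0.28, Irgm1 at -0.99 ± 0.24 and Gbp3 at -1.55 ± 0.41. Irgm1 was not called without WT coculture 3 (edgeR adjusted p = 0.0518), nor Gbp3 without WT coculture 3 or IL13KO coculture 1 or 2 (0.0732, 0.0594 and 0.0501). The list's call ended without monoculture 1 or 3, WT coculture 1 or 3 or IL13KO coculture 1 (camera adjusted p = 0.0786, 0.0591, 0.0552, 0.102 and 0.0888), with the stricter filter, the block by column number and thinning (0.0743, 0.0510 and 0.0552). Of the NRF2 targets, 0 of 12 tested genes rose and 2 fell (2 adjusted over the list alone, camera adjusted p = 0.0450, adjusted p = 0.184 with an estimated correlation), Gsta4, a glutathione transferase gene, at -3.05 ± 0.35 and Gclm, of glutathione synthesis, at -0.64 ± 0.12, while Hmox1 (-0.55 ± 0.19, edgeR adjusted p = 0.0573) and Srxn1 (-0.41 ± 0.17, 0.111) did not pass. Both were called without monoculture 1 (edgeR adjusted p = 0.00243 and 0.0363) and with only the cocultures in the fit (0.00265 and 0.0333), and Hmox1 also without monoculture 4 (0.0476), by DESeq2 (0.0308), with upper-quartile scaling (0.0454) and with the GC and length trend removed (0.0198). The list's call ended without monoculture 2 or 3, WT coculture 3 or IL13KO coculture 3 (camera adjusted p = 0.0536, 0.0571, 0.0753 and 0.0766), with the block by column number and with thinning (0.0508 and 0.0552). Not called were fibrillar matrix (5 and 9 of 22 rose and fell, camera adjusted p = 0.0813), growth factor and ERK genes (3 and 2 of 19), antigen presentation (1 and 3 of 14), ILC2 niche factors (2 and 4 of 14) and p53 targets (2 and 4 of 14). Cxcl13, a niche factor, stood at 445 ± 109 CPM with WT and 29.0 ± 3.24 with IL13KO ILC2s, and Csf1, a growth factor of macrophages, at 993 ± 69.5 and 1050.2 ± 23.4 (edgeR adjusted p = 0.810).

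Of the mural and stellate cell markers, 0 of 8 tested genes rose and 7 fell (7 adjusted over the list alone, camera adjusted p = 8.11e-06, adjusted p = 0.0275 with an estimated correlation), Rgs5 at -2.75 ± 0.22 and Pdgfrb, the PDGF receptor β, at -1.70 ± 0.27, with Kcnj8, a potassium channel gene, at -3.13 ± 0.30 and Myh11, the smooth-muscle myosin, at -2.15 ± 0.41. Of the ILC2 markers, 6 of 11 tested genes rose and 1 fell (8 adjusted over the list alone, camera adjusted p = 3.60e-04, adjusted p = 0.149 with an estimated correlation), Hlf at 3.37 ± 0.27, Arg1, or arginase 1, at 2.45 ± 0.48 and Il5 at 2.62 ± 0.66. Il13 is a member of this list, and its rise was fixed by the knockout itself. The list was not tested without Il13. The call of Il5 ended without WT coculture 3 or 4 or IL13KO coculture 1 or 3 (edgeR adjusted p = 0.0567, 0.0788, 0.0744 and 0.0587) and with the block by column number (0.0739), and without IL13KO coculture 2 it was 3.37. Of the macrophage markers, 0 of 3 tested genes rose and 1 fell (2 adjusted over the list alone, camera adjusted p = 0.0450, adjusted p = 0.177 with an estimated correlation), Lyz2 at -3.06 ± 0.15. Cd14 (-0.58 ± 0.22, edgeR adjusted p = 0.0679) and Csf1r (0.08 ± 0.19, 0.7996) did not pass. Cd14 was called without IL13KO coculture 3 (edgeR adjusted p = 0.0348), by DESeq2 (0.0494), with only the cocultures in the fit (0.0374) and with the GC and length trend removed (0.0493). The macrophage call ended without monoculture 1, 2 or 3, WT coculture 3 or IL13KO coculture 1 (camera adjusted p = 0.0763, 0.0536, 0.0664, 0.0517 and 0.0637), with the GC and length trend removed (0.0522), with the block by column number and with thinning (0.0643 and 0.0632). Of the leukocyte genes, 2 of 6 tested genes rose and 0 fell (camera adjusted p = 0.0507), Cd53 at 2.66 ± 0.18. This list was called without monoculture 4, WT coculture 1 or IL13KO coculture 1, 2 or 3 (camera adjusted p = 0.0490, 0.00200, 0.00792, 0.00116 and 0.0201). Members that rose and fell numbered 1 and 0 of 2 for T and B cells, 0 and 0 of 2 for endothelium, 0 and 1 of 2 for acinar cells, 1 and 1 of 5 for ductal epithelium, 0 and 1 of 7 for mesothelium and 0 and 1 of 3 for Schwann cells, with no call. Signs of median, mean and test differed for the T and B cell, endothelial, niche factor and ductal lists. Over the 3 comparisons, the calls that held with an estimated correlation were the type 2 response in the WT coculture against monoculture, and the type 2 response and the mural and stellate markers between the cocultures.

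**Figure D3:**
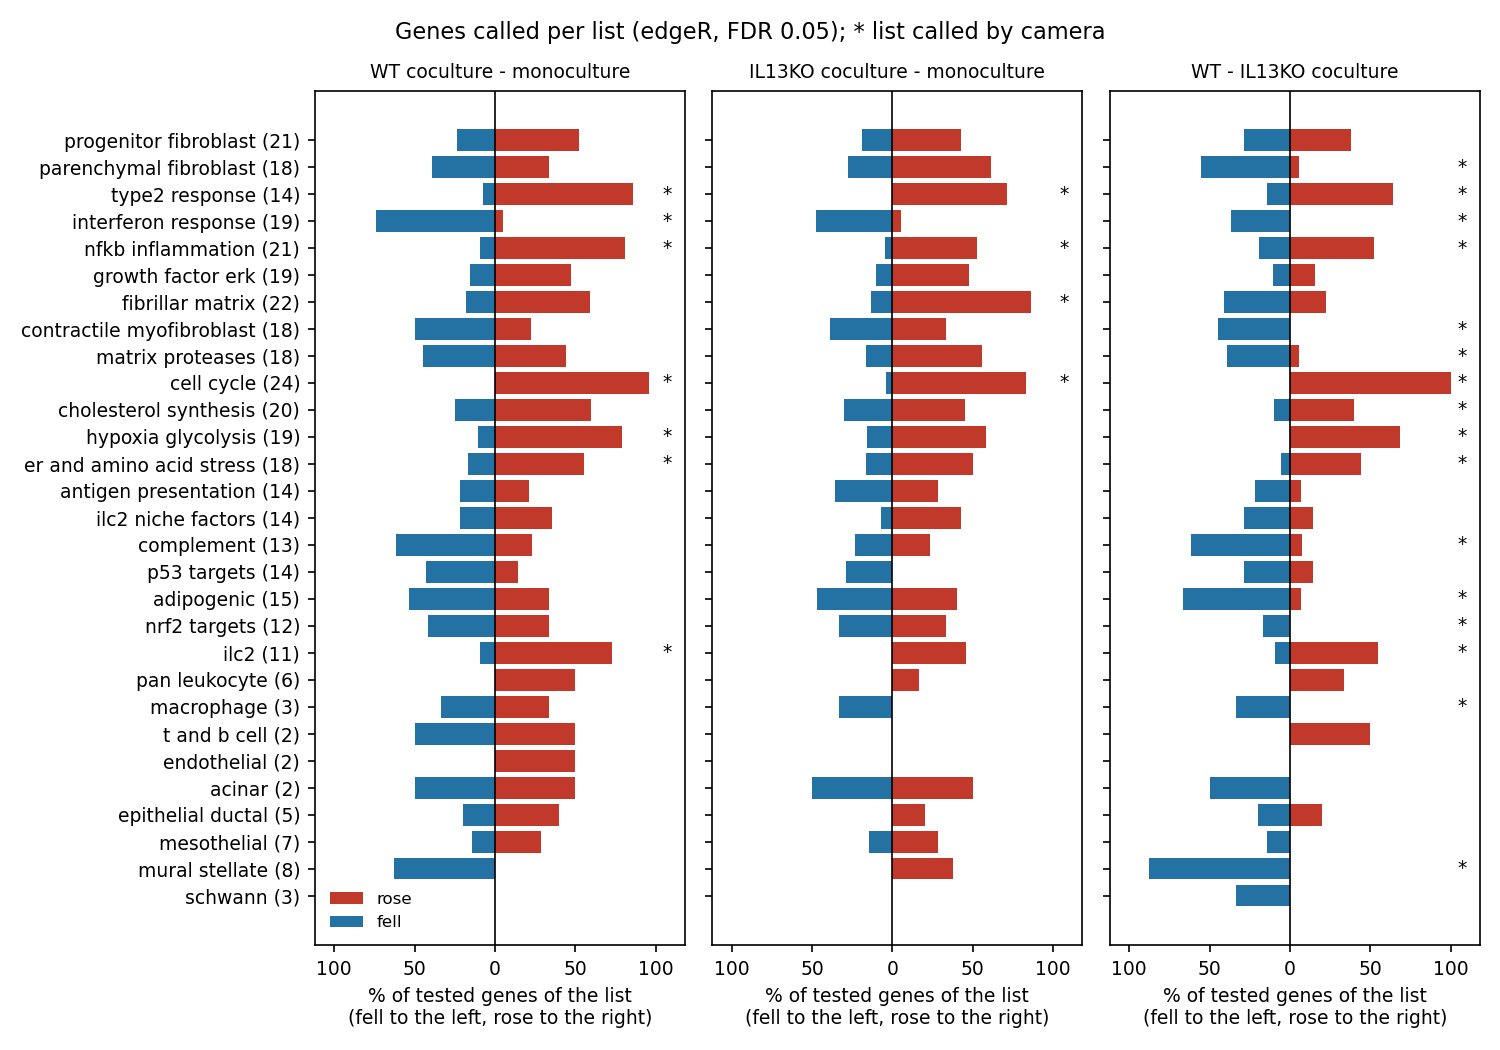
Percent of the tested genes of each list that edgeR called as higher (right) or lower (left) in each comparison, with the number tested in brackets and a star where camera called the list at its preset correlation (7, 4 and 16 lists). With an estimated correlation 1, 0 and 2 of these calls remained.

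Between the cocultures edgeR called 3810 of the 16344 genes (23.3%), 1901 higher and 1909 lower with WT ILC2s. Of the 5355 genes that rose with WT ILC2s, 1363 were called higher than with IL13KO ILC2s, of which 653 also rose in the IL13KO coculture and 664 were not called there. The count depended on single libraries, with 2523 calls without WT coculture 4, 2482 without IL13KO coculture 1 and 2337 without IL13KO coculture 2. It was 5806 with only the cocultures in the fit, 2124 with a block by column number, 1109 in a test against a fold change of 1.5 and 845 with the leukocyte level as a covariate, which differs between the groups compared. With that covariate Arg1, Cdh11, Col15a1, Dpp4, Gbp2, Gbp3, Gclm, Hsd17b7, Ifi47, Il13, Il33, Il5, Irgm1, Ly6c1, Myh11, P4ha1, Pdgfrb, Slc2a1, Tgfbi, Tpi1 and Vcam1 were not called (edgeR adjusted p from 0.0618 to 0.880). Of these, only Arg1, Il13 and Il5 moved by over 1.5 times in fold (1.26, 6.94 and -0.24). For the others the lost call does not show that the leukocyte level accounts for the difference. Clu, Col6a5, Ddx4 and Grem1, still called, moved by over 1.5 times in fold (-4.10, 5.11, 4.01 and -4.69). As far moved Cemip without WT coculture 3 (-5.89), Ddx4 without IL13KO coculture 2 (5.597), Gpbar1 without IL13KO coculture 3 (6.16) and Col6a5 without IL13KO coculture 2 (7.75) or with the block by column number (7.62). Chil3 and Chil4, with no read in a group, had fitted values of 10.65 and 15.19 by edgeR and 8.62 and 13.19 by limma-voom.

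Across the 16344 genes, fold changes over monoculture in the WT and IL13KO cocultures had Pearson's r = 0.831 and covariance 1.41. Genes are not independent replicates, and both comparisons share their 4 monocultures. In 20 draws all 10 libraries, the monocultures included, were simulated from the monoculture means without differences between groups. They gave a mean r of 0.475 and a mean covariance of 0.0592, with no gene called in both. Genes were drawn independently and without a GC and length trend. In the data that trend differed, with a mean rho with GC content of -0.313 in monoculture, 0.250 in WT and 0.355 in IL13KO cocultures. What r such a trend would give was not simulated. With the monocultures split 2 and 2, r was 0.693 to 0.739 and the covariance 1.37 to 1.41. Genes that rose in both cocultures numbered 4059 (1614 for independent lists), and 3457 fell in both (1325 for independent lists). The figures for independent lists leave the shared monocultures and the GC trend out of account. With the monocultures split 2 and 2, 3424 to 3504 genes rose in both and 2759 to 2872 fell in both.

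**Figure D4:**
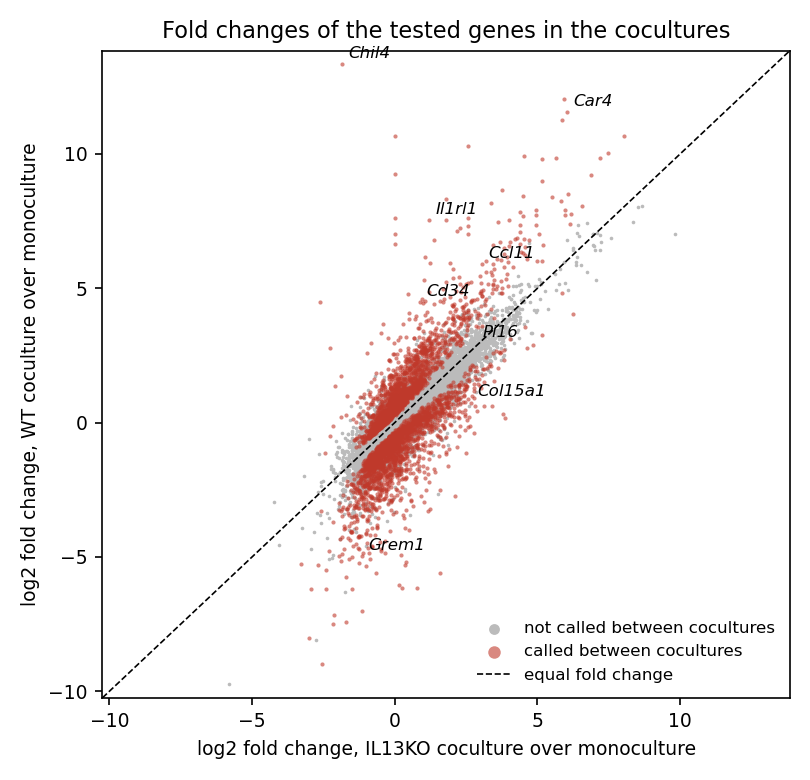
Log2 fold change over monoculture of each of the 16344 tested genes in the IL13KO (x axis) and the WT coculture (y axis), with red points for the 3810 genes called between the cocultures and a dashed line for equal change. Pi16 lies near the line and Il1rl1, Ccl11 and Cd34 above it, and fitted values of genes with no reads in a group, such as Chil4, depend on a prior count.

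The mean log2 CPM of the leukocyte list was -1.32 ± 0.300 in the monocultures, 0.36 ± 0.48 in the WT and -0.67 ± 0.35 in the IL13KO cocultures (SD, n = 4, 3 and 3). WT cocultures lay 1.68 above monocultures (exact two-sided permutation p = 0.0286, the smallest possible), and IL13KO cocultures 0.65 above them (exact p = 0.0857). Between the cocultures the level differed by 1.02 (exact p = 0.1, the smallest that 3 against 3 libraries allow). For the ILC2 list the differences were 1.94 (exact p = 0.0286), 0.67 (exact p = 0.0286) and 1.27 (exact p = 0.1). That list holds Il13, so a part of the difference between the cocultures was fixed by the knockout.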

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

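The tests of ILC2 carry-over were chosen after the results were seen, as were the alternatives that remove the GC and length trend or thin the libraries; the splits of libraries were planned.

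Single monocultures stood apart from the other 3 in CPM for 17 of the 153 genes and measures examined. Chance sets apart about 1 in 20 of independent values with a normal spread, which these CPM are not, so no excess is shown. A single read in 1 library and 0 in the others always stands apart. Monoculture 3 stood apart for Il4ra (76.2, others 46.4 to 48.3), Loxl1 (176.7, others 80.8 to 94.1), Mcm2 (10.68, others 3.21 to 4.29), C4a (1.289, others 0.632 to 0.7399), Tmem108 (2.21) and Ddx4 (0.8289). Monoculture 2 stood apart for Rtp4 (47.3, others 9.95 to 14.5), Ifi47 (39.96, others 20.5 to 21.3), Tcf21 (24.86, others 31.5 to 32.9), P4ha1 (355.4), Clu (42.8) and Chil4 (0.0740, a single read). Monoculture 1 stood apart for Saa3 (1669, others 1247 to 1303) and Ctla2a (294.6, others 205.8 to 220.9). Monoculture 4 stood apart for Nt5e (0.702), Arg1 and Il2ra (0.0702 each, a single read).

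Fold changes over monoculture differed in sign between the cocultures, by the test between them, for 94 genes called in both. Among them Podn, a proteoglycan gene, was -3.08 and Lrg1, an acute-phase gene, -2.98 in the WT against the IL13KO coculture. The rise of Podn with IL13KO ILC2s (1.36) was not called with the GC and length trend removed (0.43, edgeR adjusted p = 0.0518).

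Most tested genes were called in each coculture against monoculture. A GC content and length trend as the whole cause is argued against by 9721 and 8217 genes called with each library's trend removed, with 79.4 and 69.3% of the original calls kept. A further 55 and 92 original calls turned to the opposite direction. Libraries simulated with only that trend gave 2967 and 3968 calls uncorrected. Correction left 2 and 3 there, a result built in, since the trend was simulated from the same fit. In the data the correction left a rho with GC content of 0.082 and 0.116 (0.339 and 0.404 before). The trend as a part of the cause therefore stays open. Lower monoculture depth is argued against by 9728 and 9018 calls after thinning to equal depth. Only the real split of 35 gave as many calls in each comparison (10212 against at most 6317, and 9384 against at most 6334). This cannot exclude chance, since each other split mixed the groups, which widens the spread within a side and mostly gave 0 calls. Nor can it tell ILC2s from a day or batch that followed the groups, which the labels do not give. For the 3810 calls between the cocultures, 10 splits are too few. Other splits gave at most 0 calls by edgeR there, and at most 504 genes at an unadjusted p below 0.05. A response of the fibroblasts to ILC2s may account for the rest, and was not tested separately.

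In the WT coculture 8 of 11 ILC2 and 3 of 6 leukocyte genes rose. RNA carried over from ILC2s should follow Il5, whose CPM in WT libraries 3 and 4 was 4.55 times that in library 1 (interval 3.60 to 5.81), if Il5 per ILC2 is constant. The abundant genes Il1rl1, Hlf and Cd53 had a median ratio of 1.02 and none reached that interval, which argues against carry-over as their main source on that assumption. Genes of the 2 lists that had no monoculture read and were too low to test did not settle the assumption. In WT libraries 1, 3 and 4 Rac2 had 10, 14 and 15 reads and Ptprc 6, 3 and 9, but Klrg1 had 0, 6 and 10. Csf2 had 1, 4 and 20, Laptm5 5, 3 and 16, Il7r 0, 0 and 5, Ccr8 0, 0 and 4 and Vav1 0, 1 and 4. Cd52, untested and with 3 reads in monoculture 3, had 7, 43 and 44. Of 6 less abundant genes (median ratio 1.53), the upper bounds of 5 (1.59 to 2.34) lay below the Il5 interval too. Il2ra at 3.32 (interval 1.90 to 6.18) reached it. A mix of fibroblast and ILC2 RNA would give a ratio in between, and Arhgdib and Srgn had 9.38 and 9.53 CPM in monoculture, which could hide a small share. Carry-over as a part of the reads therefore stays open for all 6. The CD45-positive gate that the design text states would not, by that marker, remove ILC2s. Yet Ptprc, which encodes CD45, had only 6, 3 and 9 reads in the WT cocultures. A response of the fibroblasts to ILC2s may account for the abundant genes, and was not tested separately.

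Of 14 type 2 response genes, 10 rose in the IL13KO coculture too. The GC and length trend is argued against by a median log2 fold change of 2.698 with the trend removed (3.14 before), with 10 of 10 genes still called. Other ILC2 products, such as IL-4, may raise these genes and were not tested. Il4 had 6, 3 and 4 reads in the IL13KO cocultures, 2, 1 and 3 in the WT cocultures and 10, 4, 3 and 11 in the monocultures. The RNA was that of sorted fibroblasts, so these reads do not show how much IL-4 the ILC2s made.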

How the results depend on the processing

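The alternatives with the GC and length trend removed, thinning to equal depth and the block by column number were chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported ones under other size factors, DESeq2, limma-voom, both filters and without leukocyte genes (9949 to 10457 for the WT coculture, 9139 to 9753 for the IL13KO coculture and 3591 to 4428 between cocultures). Against a fold change of 1.5 they were 5884, 4234 and 1109, since the test asks for more. Between the cocultures the count was 5806 with only those groups in the fit, 2124 with the block by column number and 845 with the leukocyte level as a covariate. The main fit shares its estimate of spread with the monocultures, which lay further apart (mean distance 95.3) than the WT and IL13KO cocultures (56.0 and 50.8). Without single monocultures the count between the cocultures was 3755 to 4814. The cause of these differences was not tested. The replicate numbers do not pair libraries (residual correlations from -0.126 to 0.028 for libraries of the same column number and -0.153 to 0.140 for others). Without single libraries the counts were 9070 to 10459, 7891 to 9727 and 2337 to 4814, and called lists 5 to 8, 4 to 5 and 13 to 17. With an estimated correlation 1, 0 and 2 lists were called, and fry, which does not compare lists with other genes, called 26, 18 and 19. The correlation of fold changes was 0.711 with split monocultures (2 controls for each coculture rather than 4, the cause not tested), 0.797 to 0.850 without single libraries and 0.810 with the GC and length trend removed, the cause of the last not tested either. Col15a1 in the WT coculture turned to -0.206 with that trend removed (edgeR adjusted p = 0.488), as did Csf1r to -0.24, Icam1 to -0.18 and Itga11, from 0.34, to -0.47 (0.286, 0.256 and 0.0350). Il5 between the cocultures turned to -0.24 with the leukocyte level as a covariate, which differs between those groups. Upper-quartile scaling moved the median of all genes by -0.121 and -0.104 in the comparisons with monoculture. The leukocyte difference from monoculture was 1.44 to 1.91 for WT without single libraries, too few to reach 0.05 (smallest exact p 0.1 or 0.0667), and for IL13KO it was 0.670 with the ILC2 list (exact p = 0.0286). In simulated data a 2-fold change was found for 68, 60 and 60% of changed genes, and 6.45, 6.90 and 5.41% of calls were unchanged genes. These data held 200 changed genes of 16344, drawn independently and without a GC and length trend. Libraries simulated with only that trend gave 2967 and 3968 calls against monoculture, so these shares do not describe the real comparisons with monoculture.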

Other observations

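The gene groups here were chosen after their values were seen. Of 9 acute-phase genes tested, 0 rose and 8 fell with WT ILC2s, 4 rose and 1 fell with IL13KO ILC2s, and 7 were lower with WT than with IL13KO ILC2s by edgeR. Hp, or haptoglobin, stood at 297 ± 46.7 CPM in monoculture, 105 ± 18.8 with WT and 394 ± 36.4 with IL13KO ILC2s, and Lrg1 at 32.1 ± 7.10, 14.1 ± 3.48 and 112 ± 30.8 (SD, n = 4, 3 and 3). Of 5 collagen VI chain genes, 5 rose with WT and 4 with IL13KO ILC2s, and 4 were higher with WT than with IL13KO ILC2s. Col6a2 stood at 41.5 ± 15.7, 1173 ± 101 and 339.7 ± 60.8 CPM.

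Of 10 genes of BMPs and their antagonists, 3 rose and 5 fell with WT and 3 rose and 1 fell with IL13KO ILC2s. Of 7 carbonic anhydrase genes, 3 rose and 2 fell with WT ILC2s. Of 4 nuclear noncoding RNAs, 1 rose and 1 fell in each comparison, and Malat1 stood at 2532 ± 711, 417 ± 93.1 and 1217 ± 253 CPM.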
